A study of Mus musculus with 12 samples.

How the data were processed

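Total RNA from sorted post-selection double-positive thymocytes of 3 genotypes was prepared with a column kit, labelled with biotin and hybridised to Affymetrix whole-transcript arrays, per the labels' protocols. The 12 samples were grouped by the genotype in their labels, as WT (n = 5), PTEN KO (n = 3) and PTEN/Stat3 dKO (n = 4). Replicate numbers only name the samples and pair none of them. The labels used here give no batch, litter or scan date. The order of the columns was used only for the last 4 samples as a block and for fits of the first 8 and of the last 4.

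The authors deposited 1 table of log2 expression values. RMA and Affymetrix Expression Console 1.1 are named in the submitters' processing notes. RMA corrects background, normalises quantiles between arrays and summarises the probes of each set. It makes the arrays alike in overall distribution, so a shift of most genes in one direction would not show. The table held 28846 rows and 12 columns, and 0 columns had no sample. Of the rows, 6640 were control probe sets (5222 negative and 1324 positive among them) and 22206 transcript probe sets. The platform annotation gave exactly 1 gene symbol for 19572 of these and several for 0, and 2634 were not listed in it. All 19572 were found by Entrez identifier in the reference gene table of assembly GRCm38.p6, which changed 0 symbols. They cover 19505 genes, and 55 genes have more than 1 probe set. The reference table was used only for names and for which genes neighbour each other. A total of 0 probe sets were named Pten and 1 was named Stat3.

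The values were used as deposited, with no filter on dim probe sets. A linear model with the 3 group means was fitted to all 12 samples with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided moderated tests), which leaves 9 residual degrees of freedom. The 3 comparisons were PTEN KO against WT, dKO against WT and dKO against PTEN KO. The threshold was a Benjamini-Hochberg adjusted p under 0.05 over the named probe sets of a comparison. Fold values are 2 raised to the log2 difference, and SE is the moderated standard error.

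The following choices were made before the data were examined. The genes named are Pten and Stat3, the 8 highest and 8 lowest differences among genes past the threshold whose samples do not overlap, the members with the smallest p of each list described (2 to 4, or up to 3 for lists of other cells), and the 8 genes with the largest differences in each overlap. Predicted genes, small RNAs, olfactory, vomeronasal and antigen receptor genes were to be passed over among the highest and lowest. For a gene with several probe sets the one with the highest mean is used. A set of 37 gene lists was fixed, 26 of thymocyte programs, 10 of other cells and 1 of tissue handling. They have 807 entries, of which 727 were measured, and 4 lists had under 80% measured. Lists were tested with camera from limma at a preset inter-gene correlation of 0.01, adjusted over the 37 lists, and again with a correlation estimated for each list. Which lists the text describes was chosen after the results were seen, as those past the threshold with the preset correlation, with the FOXO list added to 2 comparisons and the type 17 list to 1.

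The share of the PTEN KO difference kept in the dKO is a slope through the origin over the genes past the threshold in PTEN KO against WT. For shared samples, 100 sets of unchanged groups were simulated from the residual covariance of the genes, and the WT samples were split into 2 and 3 in 20 ways. The procedure was tested on simulated data with 100 genes changed by 0.5 and 100 by 1 on the log2 scale among 19572. Of these it called 65% and 99% for PTEN KO against WT, 71% and 96% for dKO against WT, and 58% and 97% for dKO against PTEN KO. It made 7, 13 and 2 false calls. The simulated noise was independent between genes, without the correlation between genes in the data. These shares may therefore not hold for the data, and a gene that did not pass is not shown to be unchanged.

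Array quality was checked on the control probe sets. The median of the negative controls was 6.77 to 7.13 per array, with a mean of 6.97. Their 95th percentile was 9.83 to 10.13 per array, and 15.6% to 20.5% of the named probe sets lay above it. A level above 6.97 is therefore not by itself clear of the negative controls. Correlations between arrays of a group were 0.989 to 0.996, and 0 pairs were identical. In limma's array weights dKO replicate 1 had 0.33 and PTEN KO replicate 3 had 0.63. Depth does not apply to arrays, and their number limits the precision.

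Alternatives were a filter that left out the dimmest 40% of probe sets, quantile normalisation again, centring each array on its median, an intensity trend with a robust prior, array quality weights, fits of the compared groups alone, each sample left out in turn, every row of the table, 1 row per gene, a minimum difference of 1 on the log2 scale and an adjusted p under 0.01. For the lists they were an estimated correlation, the rotation test fry, and lists without members shared with another list. A further 7 were added after the data were seen. These were the separation of positive and negative control probe sets as a covariate, the 2 arrays of lowest weight left out, the mean of the macrophage list as a covariate, the last 4 samples in the deposited order as a block, fits of the first 8 and of the last 4 alone, and the lists without Stat3. Figures were drawn with matplotlib 3.10.9.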

Results

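Gene expression was measured on 12 whole-transcript microarrays of mouse thymocytes. The cells were CD4 and CD8 double-positive thymocytes that carried surface T cell receptor and CD69, the marker of cells that have received a selecting receptor signal. They came from C57BL/6 mice of 3 genotypes. WT had 5 samples, PTEN KO (Pten deleted by a Cre recombinase driven from Cd4) had 3, and PTEN/Stat3 dKO (both genes deleted, below dKO) had 4. The WT label names no Cre or floxed allele, while the labels of the other groups name both. In the comparisons with WT, effects of Cre therefore cannot be told apart from those of the deletions. Pten encodes the lipid phosphatase that opposes PI3K, and Stat3 a transcription factor activated by cytokine receptors. The labels do not say that the samples came from separate animals, so the p-values measure the spread between these samples, which may be technical. Values are log2 RMA values, and the number of arrays limits the precision. The labels give no batch, but the last 4 samples in the deposited order (PTEN KO replicate 3 and dKO replicates 2, 3 and 4) lay apart from the first 8 on the second principal component. All WT samples are among the first 8. In total 19572 probe sets with a gene symbol were tested with limma, at a Benjamini-Hochberg adjusted p under 0.05.

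Stat3 was first examined as a check of the labels. Its level was 11.05 ± 0.08 in WT (SD, n = 5), 11.17 ± 0.04 in PTEN KO (SD, n = 3) and 9.78 ± 0.09 in the dKO (SD, n = 4). The dKO was thus 2.41-fold below WT (log2 difference -1.27 ± 0.07 SE, adjusted p = 1.5e-07) and 2.61-fold below PTEN KO (-1.38 ± 0.08 SE, adjusted p = 2.9e-07). All 4 dKO samples lay below all other samples. PTEN KO and WT differed by 0.11 ± 0.08 (SE, adjusted p = 0.90). Whether the Stat3 probes lie in the deleted exons is not given in the sources used here. Pten is not analysed here, since no probe set was named for it.

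**Figure D1:**
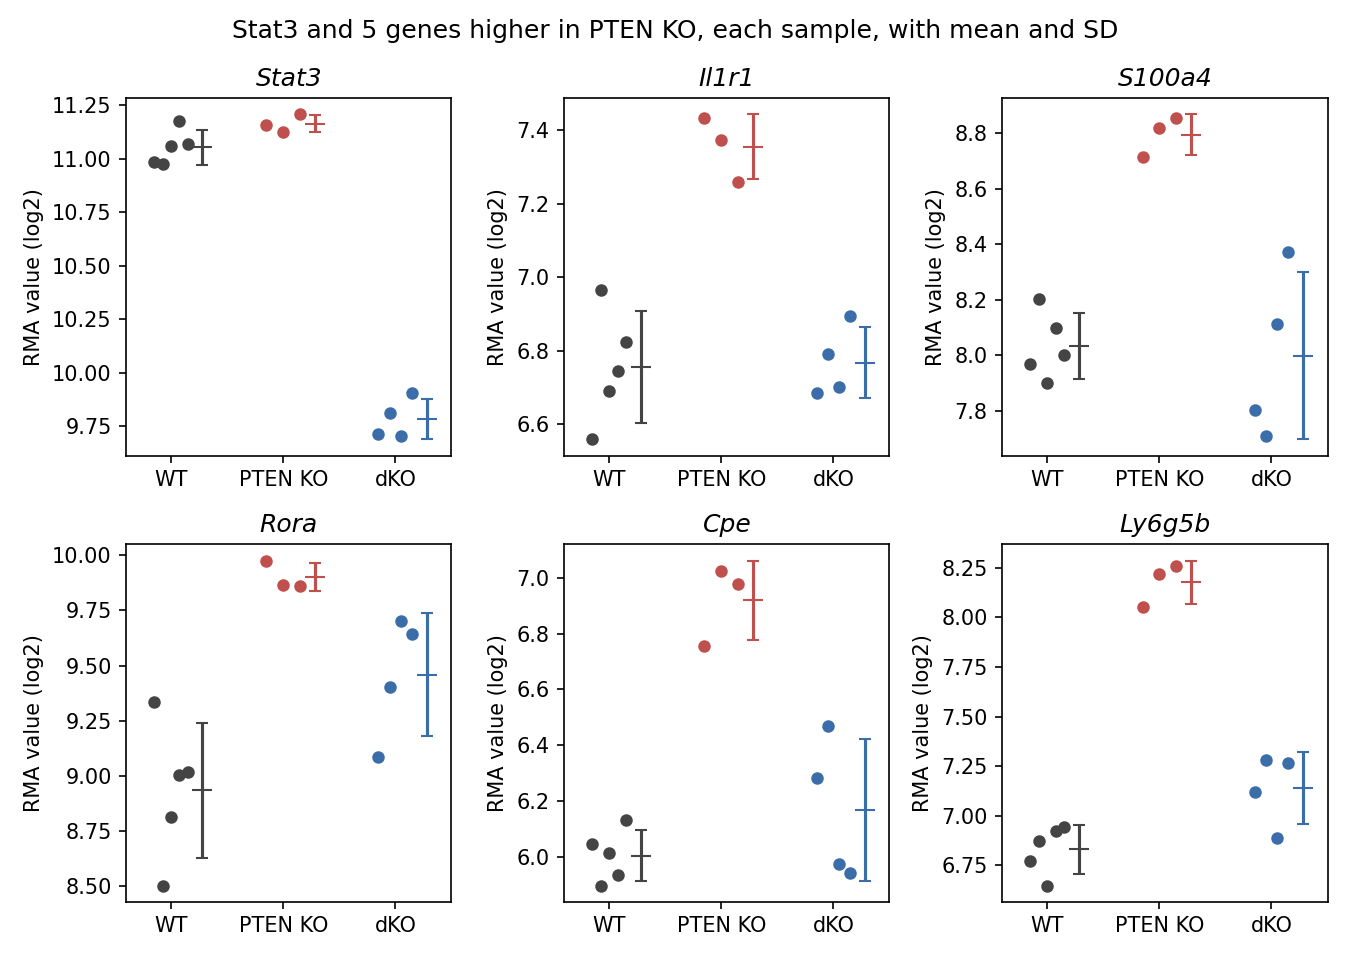
Log2 RMA value (y axis, a different range in each panel that does not start at 0) of Stat3 and 5 genes that were higher in PTEN KO than in WT, in each sample of the 3 genotypes (x axis). Points are samples and bars the mean ± SD. Stat3 was 11.05 in WT, 11.17 in PTEN KO and 9.78 in the dKO. Il1r1, S100a4, Cpe and Ly6g5b are the 4 genes that also passed in the opposite direction in the dKO against PTEN KO. They are not typical of the 39 higher in PTEN KO, of which 30 also passed in the dKO against WT.

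The comparison of PTEN KO with WT asked what differed at this stage when Pten was deleted. Among the genes that rose most, Cd44, the hyaluronan receptor, was 2.02-fold higher (log2 difference 1.02 ± 0.14 SE, adjusted p = 0.0028), and the heparan sulfate proteoglycan Sdc4 2.26-fold higher (1.18 ± 0.14, adjusted p = 0.0019). Ntrk3, the neurotrophin-3 receptor, was 2.33-fold higher (1.22 ± 0.16, adjusted p = 0.0025) and the membrane metalloproteinase Mmp14 2.18-fold higher (1.12 ± 0.18, adjusted p = 0.011). Among the genes that fell were the immunity-associated GTPases Gimap3, 2.46-fold lower (-1.30 ± 0.20, adjusted p = 0.0076), and Gimap4 (-0.91, adjusted p = 0.012).

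In all, 72 probe sets of 71 genes passed, 39 higher and 33 lower in PTEN KO. The other highest were Crmp1 (1.46), Ly6g5b (1.35), the adhesion molecule Jaml (1.05) and Tsc22d1 (1.01). In WT Crmp1 (6.66) and Ly6g5b (6.83) lay below the mean median of the negative controls, 6.97, where differences are compressed. The negative controls spread widely, with a 95th percentile of 9.83 or more on every array. Cd44 (8.75), Sdc4 (7.77), Ntrk3 (9.19) and Mmp14 (8.53) lay below that in WT. The other lowest were Plac8 (-1.22), the TGF-beta co-receptor Eng (-1.12), the sialic acid hydroxylase Cmah (-1.11), Ly86 (-0.95), the channel subunit Cnga1 (-0.94) and the B cell receptor subunit Cd79a (-0.91). In each of the 72, all 3 PTEN KO samples lay on one side of all 5 WT samples. Over all genes tested, 6.23% separated in this way, against 3.57% by chance. The count was 28 without PTEN KO replicate 3 and 39 without WT replicate 4, and 39 with every row of the value table tested. With array quality weights 100 passed. With arrays centred on their medians 31 were higher and 35 lower. With the last 4 samples as a block 87 passed, 60 of them among the 72, all 72 kept their sign and their median absolute difference was 0.70 against 0.73. In the first 8 samples alone 46 passed. Of the 24 named genes that passed, 11 passed in each of the 12 fits that left out 1 sample, among them Cd44, Sdc4, Ntrk3, Gimap3, Plac8 and Il1r1. Cnga1 passed in 2 of these fits, Ccne1 in 4, Bcl2 in 6, and Polr1b and Cd79a in 7.

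Among the gene lists, 3 programs kept their call with both ways of treating the correlation between members in camera. Genes of ribosome assembly fell. The mean of the 32 measured members was -0.24, all 32 had lower means, and adjusted p was 6.9e-22, or 0.042 with an estimated correlation. Of them 1 passed over all genes, the RNA polymerase I subunit Polr1b (-0.40, adjusted p = 0.025), and 18 were lower when adjusted over the list alone. Wdr12 (-0.41), Dkc1 (-0.48) and Noc2l (-0.35) did not pass over all genes. The mean level of the list was 10.45 ± 0.06 in WT (SD, n = 5) and 10.21 ± 0.05 in PTEN KO (SD, n = 3).

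Genes of the type 17 program, that of innate-like T cells making IL-17, rose. The mean over 29 members was 0.22, with adjusted p = 1.3e-08, or adjusted p = 0.049 with an estimated correlation. Over all genes 4 rose and 25 did not pass, and adjusted over the list alone 12 were higher and 2 lower. The 4 were the IL-17 receptor chain Il17re (0.82, adjusted p = 0.0030), the IL-1 receptor Il1r1 (0.60, adjusted p = 0.0076), the nuclear receptor Rora (0.97, adjusted p = 0.011) and the calcium-binding protein S100a4 (0.76, adjusted p = 0.011). Il1r1 lay near the negative controls, at 6.76 in WT and 7.35 in PTEN KO.

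Genes induced by T cell receptor signals during selection fell, with a mean of -0.17 over 31 members and adjusted p = 2.2e-08, or adjusted p = 0.049 with an estimated correlation. Over all genes 2 fell and 29 did not pass, and adjusted over the list alone 8 were lower. The 2 were the nuclear IkB protein Nfkbid (-0.74, adjusted p = 0.0084) and the survival gene Bcl2 (-0.42, adjusted p = 0.021). Rel (-0.34, adjusted p = 0.074) and Irf4 (-0.49, adjusted p = 0.15) did not pass.

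The calls of the other lists were lost with an estimated correlation. DNA replication genes had a mean of 0.28 over 23 members (adjusted p = 1.55e-12, or adjusted p = 0.31 with an estimated correlation), with 1 higher over all genes, the cyclin Ccne1 (0.69, adjusted p = 0.043), and 4 adjusted over the list alone. Uhrf1 (0.34) did not pass. Mitotic genes had a mean of 0.16 over 24 members (0.06 without PTEN KO replicate 3), 0 past the threshold, including Aurka (0.30) and Birc5 (0.32) (adjusted p = 0.64 with an estimated correlation). Cytosolic ribosomal proteins had a mean of -0.11 over 25 members, 0 past the threshold, including Rpl10a (-0.24) and Rps19 (-0.23) (adjusted p = 0.38 with an estimated correlation).

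The late thymic maturation list had a mean of -0.18 over 19 members (-0.12 without PTEN KO replicate 2), with Gimap3 and Gimap4 the 2 that fell (adjusted p = 0.35 with an estimated correlation), and 4 lower adjusted over the list alone. For the lists of type 1 effector, sterol synthesis and NF-kB target genes, 0 of 21, 0 of 19 and 0 of 20 members passed. Their means were 0.19 (0.07 without PTEN KO replicate 3), 0.10 (0.04 with the last 4 samples as a block) and -0.07 (-0.03 without PTEN KO replicate 2), and with an estimated correlation their adjusted p = 0.39, 0.56 and 0.53. Members with the smallest p were Klrd1 (0.76) and Il2rb (0.53), Nsdhl (0.35) and Stard4 (0.49), and Rel (-0.34) and Ltb (-0.24). Adjusted over the list alone, 0, 1 and 1 members passed.

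Targets of FOXO factors, which PI3K signalling represses, did not pass as a list (mean -0.08, adjusted p = 0.078), and 0 of 28 members passed over all genes, with 2 lower adjusted over the list alone. Tsc22d3 (-0.76, adjusted p = 0.068) and Igf1r (-0.55, adjusted p = 0.17) had the smallest p. B cell genes had a mean of -0.26 over 12 members, with Cd79a lower and Fcrla (-0.56) not past the threshold (adjusted p = 0.21 with an estimated correlation). Adjusted over the list alone, 5 were lower and 1 higher. The B cell list, one of other cells, moved in the same direction as the ribosome assembly and receptor-signal lists. Whether the sorted PTEN KO and WT cells differed in B cell RNA stays open.

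The comparison of the dKO with WT asked what differed when Stat3 was deleted as well. The largest rises again included Ntrk3, 2.92-fold (log2 difference 1.55 ± 0.15 SE, adjusted p = 3.7e-05), Mmp14, 2.72-fold (1.44 ± 0.17, adjusted p = 0.00018), and Cd44, 2.09-fold (1.06 ± 0.13, adjusted p = 0.00021). Adam11, a disintegrin-family membrane protein, rose (1.43 ± 0.11, adjusted p = 3.3e-06), as did the oestrogen-responsive gene Greb1 (1.42 ± 0.10, adjusted p = 3.3e-06). Their WT levels, 6.99 and 6.80, lay at or below the negative controls, so no fold is given. Gimap3 was 3.09-fold lower (-1.63 ± 0.19, adjusted p = 0.00016) and Plac8 2.95-fold lower (-1.56 ± 0.15, adjusted p = 3.8e-05). The complement component C1qa, made by macrophages, was 2.54-fold lower (-1.35 ± 0.17, adjusted p = 0.00031).

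Here 584 genes passed, 176 higher and 408 lower in the dKO, and 31 of them differed by at least 1 on the log2 scale. Ldlrad3 (1.30), the NK receptor chain Klrd1 (1.20, adjusted p = 0.028) and Crmp1 (1.14) completed the 8 highest. Crmp1 (6.66) and Klrd1 (6.28) lay below the negative controls in WT. Klrd1 varied between the dKO samples, at 7.48 ± 0.82 (SD, n = 4), and passed in 6 of the 12 fits that left out 1 sample. Of the 43 named genes that passed here, 35 passed in each of these fits, while Rtp4 and Nfkb2 passed in 7 and Socs1 in 8. Ly86 (-1.40), the serine protease Klk8 (-1.30), Cyria (-1.29), Stat3 and Eng (-1.27) completed the 8 lowest. In 541 of the 584 the dKO and WT samples did not overlap. Over all genes 7.03% separated, against 1.59% by chance. The count was 318 without WT replicate 4, 388 without WT replicate 3 and 352 without dKO replicate 3. With quantile normalisation again 244 were higher and 381 lower, and with arrays centred on their medians 133 and 475. With the mean of the macrophage list as a covariate 0 passed. The groups hold 85.5% of the variance of that mean, and the median SE rose to 0.232. With the last 4 samples as a block 1816 passed, 380 of them among the 584. All 584 kept their sign, with a median absolute difference of 0.47 against 0.46 and a median SE of 0.115 against 0.092. This fit rests largely on dKO replicate 1, the 1 dKO sample among the first 8, which also helped to choose the 584.

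Ribosome assembly genes were lower in the dKO as well, with a mean of -0.34 over 32 members and adjusted p = 4.3e-23, or adjusted p = 0.035 with an estimated correlation. Over all genes 17 fell, and 21 adjusted over the list alone, led by Polr1b (-0.65, adjusted p = 7.8e-05), Wdr12 (-0.68), Dkc1 (-0.73) and Nolc1 (-0.60). Late thymic maturation genes, which rise as single-positive thymocytes mature and leave the thymus, fell. Their mean was -0.42 over 19 members, with adjusted p = 2.5e-09, or adjusted p = 0.047 with an estimated correlation. Over all genes 7 fell and 8 adjusted over the list alone, among them Gimap3, Gimap4 (-1.01), the IL-7 receptor Il7r (-1.09, adjusted p = 0.0060) and Ms4a6b (-0.69).

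Genes of the receptor-signal response fell, with a mean of -0.22 over 31 members and adjusted p = 9.2e-08, or adjusted p = 0.047 with an estimated correlation. Over all genes 7 fell, and 15 adjusted over the list alone, including Bcl2 (-0.54, adjusted p = 0.00036), Nfkbid (-0.82), the costimulatory receptor Icos (-0.60) and Rel (-0.34). Macrophage and monocyte genes, a list of cells the gate should exclude, fell in the same comparison. Their mean was -0.35 over 16 members, with adjusted p = 3.6e-07, or adjusted p = 0.047 with an estimated correlation. Over all genes 5 fell, and 8 adjusted over the list alone, led by the lysosomal protease Lgmn (-0.93, adjusted p = 1.3e-05), C1qa and the Fc receptor Fcgr3 (-0.68). The mean level of this list was 8.15 ± 0.08 in WT (SD, n = 5), 8.10 ± 0.08 in PTEN KO (SD, n = 3) and 7.80 ± 0.05 in the dKO (SD, n = 4).

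Interferon-induced genes had a mean of -0.30 over 24 members (adjusted p = 5.3e-11, or adjusted p = 0.091 with an estimated correlation). Over all genes 6 fell and 18 did not pass, and 12 were lower adjusted over the list alone. Among the 6 were the GTPase Gbp2 (-0.81, adjusted p = 0.00010), Usp18 (-0.61), Bst2 (-0.47) and Rtp4 (-0.55). STAT3 target genes had a mean of -0.15 over 30 members (adjusted p = 0.0025, or adjusted p = 0.26 with an estimated correlation). Without Stat3, whose fall the genotype fixes, the mean was -0.11 (adjusted p = 0.028, or adjusted p = 0.38 with an estimated correlation). The 4 that fell were Stat3 itself, Icos, the kinase Pim2 (-0.80, adjusted p = 0.0053) and Socs1 (-0.49, adjusted p = 0.024), with 1 higher and 6 lower adjusted over the list alone. Pim2 had fallen in PTEN KO too (-0.79, adjusted p = 0.036). Of the cytokine feedback inhibitors, with a mean of -0.20 over 12 members, Socs1 fell and Socs4 (-0.33) did not pass (adjusted p = 0.091 with an estimated correlation).

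Of the FOXO targets 3 fell, Tsc22d3 (-0.89, adjusted p = 0.0038), Il7r and Igf1r (-0.69), and the list did not pass (mean -0.12 over 28 members, adjusted p = 0.069). The type 17 list did not pass either (mean -0.05 over 29 members, adjusted p = 0.60). It had 1 member higher and 4 lower. NF-kB targets had a mean of -0.10 over 20 members with Rel and Nfkb2 (-0.43) lower (adjusted p = 0.41 with an estimated correlation). B cell genes had a mean of -0.31 over 12 members with Cd79a (-1.11) and Cd79b (-0.50) lower (adjusted p = 0.13 with an estimated correlation). Cd79b passed in 2 of the 12 fits that left out 1 sample.

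DNA replication genes had a mean of 0.23 over 23 members (0.14 without dKO replicate 4, 0.09 with the last 4 samples as a block), with Ccne1 (0.62, adjusted p = 0.014) higher and Fen1 (0.35) not past the threshold (adjusted p = 0.40 with an estimated correlation). Mitotic genes had a mean of 0.14 over 24 members (0.01 without dKO replicate 4, -0.07 with this block), 0 past the threshold, with Birc5 at 0.41 and Kif23 at -0.38 (adjusted p = 0.58 with an estimated correlation). Cytosolic ribosomal proteins had a mean of -0.11 over 25 members, 0 past the threshold, with Rpl3 and Rpl10a both at -0.19 (adjusted p = 0.40 with an estimated correlation). Sterol synthesis genes had a mean of 0.11 over 19 members (0.05 without dKO replicate 4, 0.19 without dKO replicate 1 and -0.01 with this block), with Nsdhl (0.48, adjusted p = 0.0031) and Insig1 (0.43, adjusted p = 0.046) higher (adjusted p = 0.46 with an estimated correlation). Insig1 passed in 2 of the 12 fits that left out 1 sample.

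**Figure D2:**
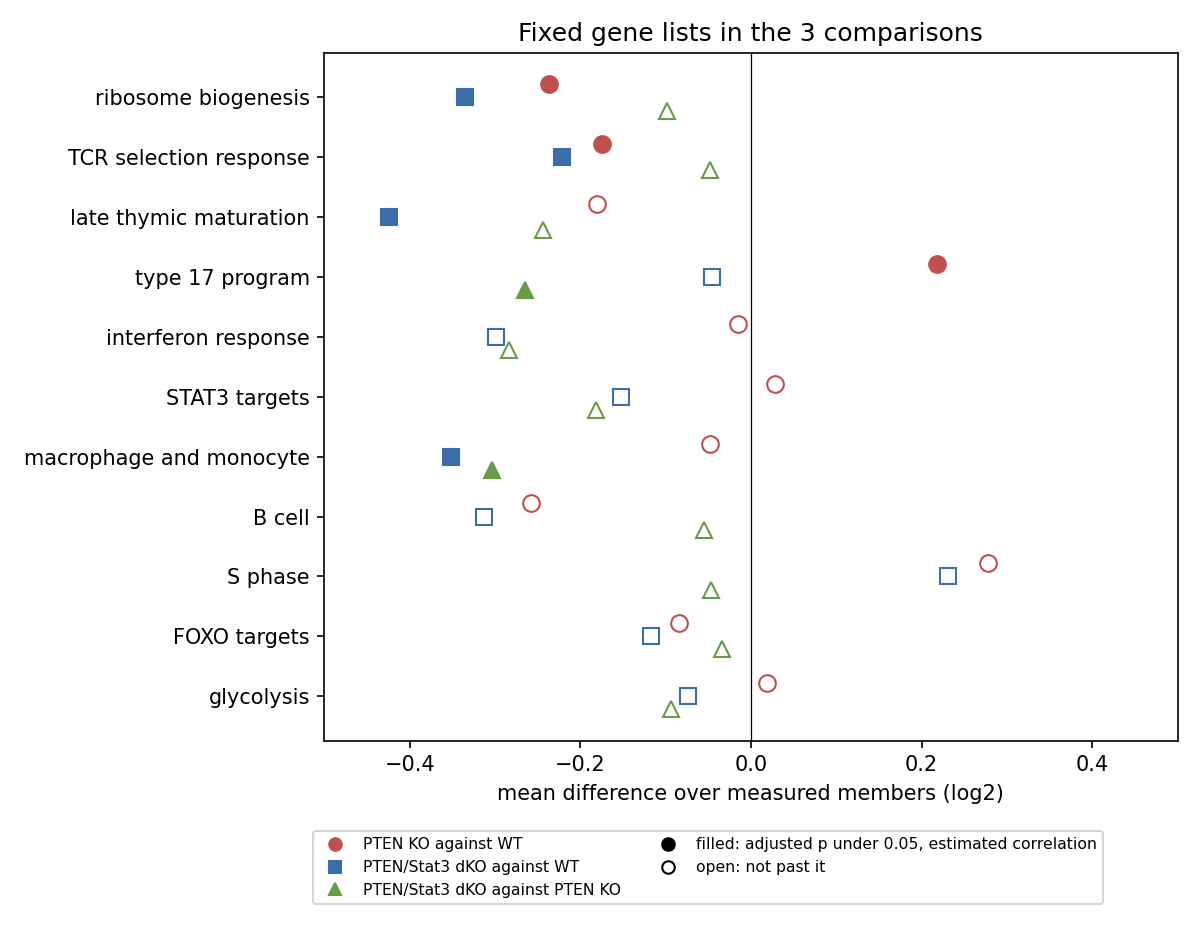
Mean log2 difference over the measured members (x axis) of 11 gene lists (y axis) in the 3 comparisons, with filled symbols for an adjusted p under 0.05 with an estimated correlation. The type 17 list lay at 0.22 in PTEN KO against WT, at -0.05 in the dKO against WT and at -0.26 in the dKO against PTEN KO.

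The direct comparison of the dKO with PTEN KO asked what the added loss of Stat3 changed. Few genes passed. Besides Stat3, Ly6g5b was lower in the dKO (log2 difference -1.04 ± 0.11 SE, adjusted p = 0.00044), S100a4 1.74-fold lower (-0.80 ± 0.13, adjusted p = 0.038) and the IL-1 receptor Il1r1 lower as well (-0.59 ± 0.10, adjusted p = 0.038). Adam11 was higher (1.11 ± 0.12, adjusted p = 0.00055), and so was Greb1 (1.09 ± 0.12, adjusted p = 0.00055).

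The 10 genes that passed, 3 higher and 7 lower, also included the meiotic gene Sycp1 (1.01, adjusted p = 0.036), the carboxypeptidase Cpe (-0.75, adjusted p = 0.035), Lgmn (-0.59, adjusted p = 0.022) and the dNTP hydrolase Samhd1 (-0.58, adjusted p = 0.015). Sycp1 and Cpe lay below the negative controls (6.97) in both groups. In the group with less signal Il1r1 lay below them too (6.77), and Ly6g5b (7.14), Greb1 (7.13) and Adam11 (7.31) close above. The 4 dKO and 3 PTEN KO samples did not overlap for any of the 10. Over all genes 4.68% separated, against 5.71% by chance. Stat3, Ly6g5b, Adam11 and Greb1 passed in each of the 12 fits that left out 1 sample and in the fit of these groups alone, and the other 6 genes did not. With the last 4 samples as a block 10 passed, 8 of them the same, without Cpe and Il1r1. The count was 4 without dKO replicate 3, and 6 without WT replicate 3, 4 or 5, PTEN KO replicate 2 or 3, or dKO replicate 2.

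Genes of the type 17 program fell in the dKO relative to PTEN KO. The mean was -0.26 over 29 members, with adjusted p = 2.2e-14, or adjusted p = 0.020 with an estimated correlation. Over all genes S100a4 and Il1r1 fell and 27 did not pass, and adjusted over the list alone 12 were lower. The IL-23 receptor Il23r (-0.76, adjusted p = 0.25) and Tmem176b (-0.47, adjusted p = 0.27) did not pass over all genes. Il23r lay below the negative controls (6.97) in every sample, at 5.37 to 6.79. The mean level of the list was 8.22 ± 0.06 in PTEN KO (SD, n = 3) and 7.95 ± 0.09 in the dKO (SD, n = 4). The macrophage list fell too, with a mean of -0.30 over 16 members and adjusted p = 1.2e-08, or adjusted p = 0.041 with an estimated correlation. Lgmn fell, 15 members did not pass, including C1qa (-1.08, adjusted p = 0.071) and Fcgr3 (-0.63), and adjusted over the list alone 4 were lower.

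Interferon-induced genes had a mean of -0.28 over 24 members (adjusted p = 1.4e-15, or adjusted p = 0.068 with an estimated correlation). Over all genes 0 passed in limma, and 8 were lower adjusted over the list alone. Gbp2 (-0.47), Usp18 (-0.58), Bst2 (-0.44) and Irf7 (-0.47) had the smallest p. STAT3 targets had a mean of -0.18 over 30 members, or -0.14 without Stat3 (adjusted p = 0.087 and adjusted p = 0.17 with an estimated correlation). Stat3 and Il1r1 fell, while Il23r, below the negative controls in every sample, and Mcl1 (-0.25) did not pass. Adjusted over the list alone, 3 were lower. Cytokine receptors had a mean of -0.18 over 24 members (-0.11 without dKO replicate 1), with Il1r1 lower and Il23r not past the threshold (adjusted p = 0.16 with an estimated correlation).

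In the remaining lists with a call, 0 members passed over all genes. Late thymic maturation genes had a mean of -0.24, with S1pr1 at -0.45 and Slfn1 at -0.43 (adjusted p = 0.15 with an estimated correlation). Ribosome assembly genes had a mean of -0.10, with Polr1b at -0.25 and Wdr12 at -0.27 (adjusted p = 0.27 with an estimated correlation). Glycolysis genes had a mean of -0.09, with Slc2a3 at -0.37 and Tpi1 at -0.28 (adjusted p = 0.23 with an estimated correlation). With the mean of the macrophage list as a covariate Slc2a3 reversed to 0.13. Type 1 genes had a mean of -0.15 (-0.04 without PTEN KO replicate 3, and reversed in camera without the 2 arrays of lowest weight), with Gzma at -1.39 and Gzmb at -0.51 (adjusted p = 0.41 with an estimated correlation). Cytokine feedback inhibitors had a mean of -0.11 (-0.06 without dKO replicate 1), with Socs1 at -0.19 (0.16 in the last 4 samples alone) and Ptpn6 at -0.13, and thymic epithelial genes one of 0.09 (0.06 without dKO replicate 1), with Prss16 at 0.42 and Krt14 at 0.24 (adjusted p = 0.23 for both with an estimated correlation).

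The series title describes the Stat3 deletion as a rescue, so the genes that differed in PTEN KO were followed into the dKO. A set of 4 genes higher in PTEN KO was lower again in the dKO by the direct test, Ly6g5b, Cpe, S100a4 and Il1r1. In the direct test Ly6g5b passed in all 12 fits that left out 1 sample, Cpe in 4, Il1r1 in 3 and S100a4 in 2. Over these fits S100a4 stayed lower in the dKO, at -0.92 to -0.70, with an adjusted p of up to 0.19 in limma. Its call therefore depends on single samples. In the dKO S100a4 differed from WT by -0.04 ± 0.11 (SE). Cpe lay below the negative controls in all groups, Il1r1 in WT and the dKO and Ly6g5b in WT, so for these 3 genes no return to the WT level can be read. Both comparisons share the PTEN KO samples, and part of this overlap may come from that. Independent lists would share 0.019 genes, a value that leaves out the shared samples. Simulated groups with no changed genes gave 0 in each of 100 draws, a value that leaves out the effects and is fixed by the lack of calls. The overlap was 1 gene in the fits of the compared groups alone, 2 with the last 4 samples as a block and 1 to 4 when 1 sample was left out.

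Most genes that differed in PTEN KO differed in the same direction in the dKO. Of the 72, 71 had the same sign against WT in both, and 62 passed in both, 30 of the 39 higher and 32 of the 33 lower. Those with the largest differences in both were Gimap3, Ntrk3, Plac8, Crmp1, Eng, Mmp14, Cmah and Sdc4. The slope of the dKO difference on the PTEN KO difference over the 72 was 0.99, with an SD of 0.04 over fits that left out 1 sample. These fits share most samples, so this SD is not a standard error of the slope. The slope was 0.84 over the higher and 1.20 over the lower genes.

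Both differences use the same WT samples, which adds to such agreement. Any effect of Cre, which both other groups carry, would add to it as well. Simulated groups with no changed genes had the same sign in 81.5% on average (from 0% to 100%), against 98.6% observed, and a mean slope of 0.32 (from -0.795 to 1.29). They gave 0 genes in both for lack of calls, and independent lists, which leave out the shared samples, would share 1.04. WT was also split so that each comparison had its own samples. The median slope over 20 splits was 0.81 (from 0.46 to 0.94) and the median overlap 13 genes (from 2 to 25). Each comparison then had only 2 or 3 WT samples, and 3 to 54 genes passed in PTEN KO against WT, against 72 with all WT samples. The smaller overlap therefore does not measure the sharing of WT samples alone. Over all probe sets the differences correlated across genes, which are not independent replicates, at r = 0.684 against a simulated mean of 0.342 (from -0.704 to 0.900), and with WT split at a median of 0.427 (from 0.337 to 0.513). The covariance was 0.0159 against a simulated mean of 0.0046 (from -0.0097 to 0.0185). The observed slope, sign share, r and covariance all lay within the simulated ranges. The overlap was 23 genes without PTEN KO replicate 3, 32 without WT replicate 4 and 39 without WT replicate 1.

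**Figure D3:**
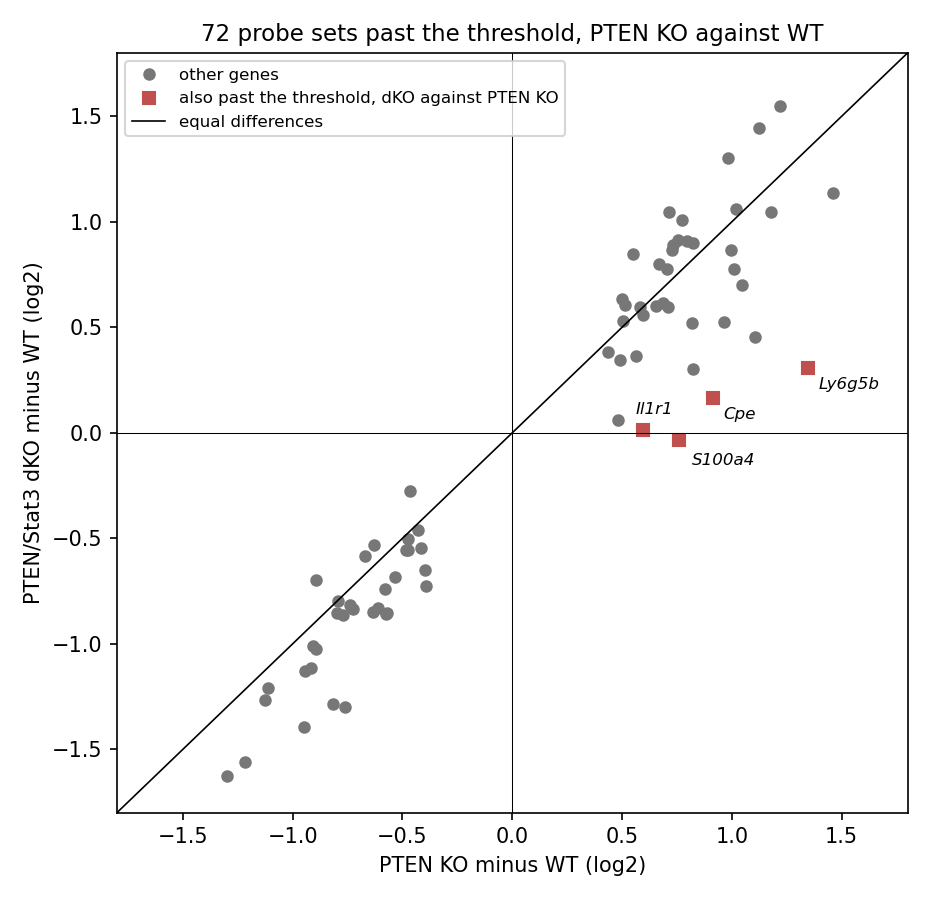
Log2 difference from WT in PTEN KO (x axis) and in the dKO (y axis) of the 72 probe sets that passed in PTEN KO against WT, with a line of equal differences. Red squares are the 4 genes that also passed in the dKO against PTEN KO; 71 of the 72 have the same sign on both axes.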

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

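The tests of an array that stood apart, of the number of samples, of array signal and of the order of the samples were chosen only after the results they measure were seen; the others were planned.

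In 8 of 216 groups of values examined 1 sample lay far from the others of its group, where about 5% would by chance. For single genes these were Bcl2 in WT replicate 2, at 11.69 with the other WT samples at 11.82 to 11.86, and Ptpn6 in WT replicate 1, at 11.69 with the others at 11.73 to 11.74. In dKO replicate 4, Irf4 was 8.02 with the next at 7.57, and Nfkb2 10.59 with the others at 10.16 to 10.21. In dKO replicate 1, Insig1 was 8.86 with the others at 9.39 to 9.44. For list means, all in dKO replicate 4, they were cytosolic ribosomal proteins at 12.80 (others 12.66 to 12.68), type 1 genes at 8.16 (others 7.82 to 7.84) and NF-kB targets at 9.95 (others 9.79 to 9.81).

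Of the 2634 transcript probe sets without a gene name, which the report does not use, 4 differed between PTEN KO and WT, all lower. Between dKO and WT 35 differed, 8 higher and 27 lower, and between dKO and PTEN KO 1 was lower. Of the 6640 control probe sets 0, 4 and 3 passed in these comparisons.

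Other splits of the samples into groups of the same sizes were counted for each result. In PTEN KO against WT, 1 of 56 splits, the real one, gave as many genes (72, highest other 1). In dKO against WT 1 of 100 drawn did, again the real one (584, highest other 29). Chance is argued against for both counts but not excluded, since these tests could give no smaller share. The other splits also mix genotypes, which widens the spread and lowers their counts. In dKO against PTEN KO 2 of 35 splits gave as many genes (10, highest other 12), so chance stays open there. For the number of lists chance stays open in every comparison. As many lists came from 4 of 56 splits in PTEN KO against WT (11, highest other 12), 14 of 100 drawn in dKO against WT (13, highest other 18) and 8 of 35 in dKO against PTEN KO (11, highest other 17).

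Macrophage genes were lower in the dKO than in WT, though the gate should exclude macrophages. The 1 dKO array that stood apart is argued against as the cause, since without it the list mean was -0.36 (adjusted p = 2.1e-07). Less macrophage RNA in the sorted dKO cells stays open. Within groups the members rose and fell together more than 96.1% of 1000 random lists matched on level. The B cell list, with lower means in both comparisons with WT, stood at 98.3%, and the regulatory T cell list at 98%. The random lists were matched on level only, so a high value does not single out RNA of other cells. Of the 5 macrophage members with the highest level in WT, Ctss, Lgmn, Apoe and C1qa fell and C1qb did not pass (-0.47, adjusted p = 0.057). Tyrobp (8.23 in WT, 8.24 in the dKO) and Sirpa (8.51 and 8.52) did not fall. A change inside the thymocytes by genotype stays open too and was not tested.

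The 100 nearest named genes on each side of the deleted genes were examined, and Adam11 lies 65 genes from Stat3. Around Pten 0 of the 200 nearest genes passed in PTEN KO against WT, with 0.74 expected from the share elsewhere (0.37%, Fisher p = 1). For Stat3, 9 of 200 passed in dKO against WT (4.5%) against 574 of 19304 elsewhere (2.97%, Fisher p = 0.21). In dKO against PTEN KO 1 of 200 passed, Adam11, against 8 of 19304 elsewhere (Fisher p = 0.089). Too few neighbours passed, or were expected to, for any of these tests to decide whether DNA of another strain around these alleles contributed. For Pten a share at or below that elsewhere had been set as evidence against it, which was wrong with so few expected. An effect of Stat3 loss on these genes stays open, untested.

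More genes passed in dKO against WT (584) than in PTEN KO against WT (72). The dKO array that stood apart is argued against as the cause, since 526 passed without it against 90 in PTEN KO. The 4 dKO against 3 PTEN KO samples are argued against by the lowest count with 3 dKO samples, 352 against 61. Array signal stays open, since the separation of control probe sets hardly differed between groups and as a covariate moved little (598 against 65). An unrecorded batch of the last 4 samples stays open too. The fit with them as a block (1816 against 87) rests largely on 1 dKO sample among the first 8. Batch and genotype therefore cannot be told apart for the dKO. All 584 genes kept their sign, at a median absolute difference of 0.47 against 0.46. That says little here, since the same dKO sample helped to choose the 584. The added loss of Stat3 and a difference in the sort were not tested.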

How the results depend on the processing

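The control probe covariate, the macrophage covariate, the fits without the 2 arrays of lowest weight, all fits by the order of the samples and the lists without Stat3 were chosen only after the data were seen; the other alternatives were planned. Of 2780 repeats for 120 named gene results, 2482 kept direction and side of the threshold, 267 no longer passed, 29 newly passed and 2 reversed. Of 973 repeats for the lists these were 823, 141, 3 and 6. Unless a reason is given, the cause was not tested.

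The numbers of genes were 72 in PTEN KO against WT, 584 in dKO against WT and 10 in dKO against PTEN KO, with 62 in both comparisons with WT and 4 in opposite directions. With fewer genes passing by construction, a minimum of 1 on the log2 scale gave 13, 31 and 5 genes, with 9 in both and 1 opposite, and an adjusted p under 0.01 gave 28, 201 and 4, with 24 and 1. Testing every row of the table gave 39 in PTEN KO against WT, 32 in both and 1 opposite. The intensity trend gave 112 in PTEN KO against WT and 95 in both. Fits of the compared groups alone, which use fewer samples, gave 4 in dKO against PTEN KO and 1 opposite. Without the dimmest probe sets 2 were opposite, and 2 without the 2 arrays of lowest weight. WT split into 2 and 3 samples, which leaves fewer WT samples in each comparison, gave a median of 13 in both. The split by direction moved with the scaling. In PTEN KO against WT it was 39 higher and 33 lower as deposited, 39 and 27 with quantile normalisation again and 31 and 35 with arrays centred, and in dKO against WT 176 and 408, 244 and 381, and 133 and 475.

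The slope of 0.99 was 0.95 with every row, 0.92 with the minimum of 1, 0.92 without the 2 arrays and 0.81 with WT split. Leaving out 1 sample in turn gave 28 to 90, 318 to 601 and 4 to 10 genes in the 3 comparisons, 23 to 76 in both, 1 to 4 opposite and slopes of 0.87 to 1.01. Stat3 stayed past the threshold in these, at -1.31 to -1.24 in dKO against WT and -1.42 to -1.36 in dKO against PTEN KO.

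The lists that passed numbered 11, 13 and 11. An estimated correlation left 3, 4 and 2. The rotation test fry left 3 in PTEN KO against WT and 3 in dKO against PTEN KO. Without the 2 arrays of lowest weight 7 passed in PTEN KO against WT and 6 in dKO against PTEN KO, where the type 1 list mean went from -0.155 to -0.00534, above that of the other genes, so that its direction in camera reversed (adjusted p = 0.92). Leaving out 1 sample gave 7 to 15 in PTEN KO against WT.

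With the mean of the macrophage list as a covariate, the numbers of genes were 46, 0 and 1, with 0 in both and 0 opposite, a slope of 0.77 and 4 lists in dKO against WT. Stat3 in dKO against WT was -1.17 ± 0.19 (SE, adjusted p = 0.28), against -1.27 ± 0.07 without it. The mean of the list differs between the groups, with 85.5% of its variance there, so the median SE rose from 0.092 to 0.232 and the calls ended. The median absolute difference of the 584 genes went from 0.46 to 0.38. Mitotic genes reversed to -0.18 in dKO against WT, and Slc2a3 to 0.13 in dKO against PTEN KO. The macrophage list itself was not tested with it, which would be circular. Signal over background differed little between the groups, with 4.26% of the variance of control probe separation, and as a covariate it gave 598 genes in dKO against WT. Genes near the negative controls are those that signal limits, since background compresses their differences.

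The last 4 samples in the deposited order lay at -16.5 to -8.57 on the second principal component (16.5% of the variance) and the first 8 at 1.20 to 12.2. In a fit with the genotypes, 680 genes differed between those 4 and the other samples, against 0 for each of the 11 other choices of 1 PTEN KO and 3 dKO samples, though this block was chosen for lying apart. No label says that they were processed apart. With the block 87, 1816 and 10 genes passed, 2 of them opposite, and Stat3 was -1.33 in dKO against WT and -1.42 in dKO against PTEN KO. The ribosome assembly, type 17, receptor-signal, late maturation and macrophage lists kept the calls described at the preset correlation. An estimated correlation was not used with the block. The first 8 samples alone gave 46, 2430 and 22 genes, 33 in both, 2 opposite, a slope of 0.93 and 7 lists in PTEN KO against WT, with the lone dKO sample assumed to vary like the other groups. The last 4 alone gave 4 genes in dKO against PTEN KO, with the lone PTEN KO sample assumed so too, and Socs1 reversed to 0.16. In dKO against WT the sterol list reversed to -0.00932 with the block and -0.105 in the first 8, and the mitotic list to -0.0707 and -0.0593. The cause of the structure was not tested.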

Other observations

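The gene groups and the test below were chosen after the values were seen. Of the 8 Gimap GTPase genes measured, all 8 had lower means in PTEN KO and in the dKO than in WT, with 2 past the threshold in PTEN KO and 4 in the dKO (Gimap3, Gimap4, Gimap7 and Gimap8).

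Genes of the hypoxia response went both ways in the dKO against WT, with Egln3 higher (0.92) and Ankrd37 (-0.69), Mxi1 (-0.73), Ndrg1 (-0.61) and Kdm3a (-0.34) lower. So did amino acid transporters, with Slc1a5 higher (0.47) and Slc7a5 (-0.39), Slc7a6 (-0.54) and Slc43a1 (-0.64) lower. The transcription factor Etv5 was lower in PTEN KO (-0.80) and in the dKO (-0.85), and the heat shock gene Hsph1 in the dKO (-1.15).

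In the dKO 21 of the 39 genes higher in PTEN KO lay nearer to WT than in PTEN KO, against 4 of the 33 lower genes. The hypothesis that Stat3 loss returned the higher genes more often gave a Fisher p of 0.00021, with genes that are not independent. The p was 0.31 without PTEN KO replicate 1 and 0.70 without PTEN KO replicate 3, so it rests on single samples and cannot be decided here. Genes chosen on the PTEN KO samples fall back by construction. Over all 72 the dKO differed from PTEN KO towards WT in 34.7%. Simulated groups with no changed genes gave 93.8% on average (from 13.9% to 100%). Their genes carry no effects, and the observed share lies in that range. It therefore shows neither a return of the 72 towards WT nor its absence. The test asked for a small p in every such repeat, a demand added after these values were seen.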
